A study of Mus musculus with 46 samples.

How the data were processed

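The series measured total RNA by sequencing in airway macrophages of 46 mice, 24 female and 22 male, of 6 inbred strains. The strains were C57BL/6J, a classical laboratory strain, and 5 Collaborative Cross strains, which are recombinant inbred lines made by intercrossing several founder strains: CC003/Unc, CC017/Unc, CC025/GeniUnc, CC039/Unc and CC059/TauUnc. Per the labels' protocols, mice breathed ozone at 2 ppm or filtered air during 3 hours and were killed after 21 hours of recovery. Per the labels' protocols, pelleted macrophages were lysed directly, RNA was isolated with a column kit, and stranded libraries were made from total RNA with a low-input kit (NuGEN Ovation SoLo). How the cells were pelleted or purified from the airways is not given in the sources used here.

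Per the submitters' processing notes, reads were aligned with STAR and quantified with RSEM against the mouse build mm9; versions and settings are not given in the sources used here. The deposited values used here are expected counts per gene, which RSEM estimates by dividing reads that fit several transcripts among them, per the file headers; they were not scaled, and 3.77% of them were not whole numbers. Each table lists RefSeq transcripts per gene, per the file headers. The tables of C57BL/6J listed 24485 genes, those of CC059/TauUnc 24368 and those of the other 4 Collaborative Cross strains 24402, so that 117 and 83 genes of the C57BL/6J tables were missing there, and transcript lengths differed between strains. Only the 24368 genes present in every table were compared. A table of the whole series held the same values: 1122884 values were compared with each mouse's own table and 0 differed by more than 0.005. In the series-wide one, 27 entries had names of no gene in the mouse tables and 2 names were repeated; it was used only for this check. Entries left out held at most 0.0853% of a library's counts. The genome given here was of another build, so no coordinates are printed.

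Expected counts were rounded to whole numbers. Library sizes were scaled by the trimmed mean of M-values (TMM), and genes too low for testing were removed with the default expression filter of edgeR by group, which left 12238 genes. A quasi-likelihood model with robust dispersion was fitted to all 46 mice with edgeR 4.0.16, with 12 strain-by-treatment groups and sex as terms, leaving 33 residual degrees of freedom. The common dispersion was 0.384 and the median prior degrees of freedom were 17.0. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05; adjusted p without another name below are from this test. The comparisons were the mean of the 6 within-strain ozone effects, ozone against air within each strain, the difference of the ozone effect between strains (an F test of 5 contrasts against C57BL/6J), strain differences in air (an F test of 5 contrasts against C57BL/6J), sex, and a sex-by-ozone term in an enlarged model. Fold changes are log2 with a standard error (SE), which for single genes is the absolute log2 change over the square root of its F value. This SE is approximate where a group had 0 counts, because the fold then depends on the prior count, and for changes near 0. Levels are CPM, counts scaled to a common library size with TMM factors, given as mean ± SD over mice.

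A total of 30 gene lists was fixed from textbook knowledge, and 29 had measured members; the mitochondrially encoded genes had 0 measured. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with adjustment over the 29 lists in each contrast, then with an estimated correlation, and with fry. Camera compares a list with all other genes, and fry asks whether its members move one way on balance. The lists were: NRF2 antioxidant targets; inflammatory cytokines and chemokines; type I interferon response; cell cycle and proliferation; cholesterol synthesis; LXR targets and lipid handling; resident alveolar macrophage identity; recruited and monocyte-derived macrophages; monocytes, neutrophils, airway and alveolar epithelium, T and NK lymphocytes, B lymphocytes, eosinophils, dendritic cells, and erythroid cells and platelets as markers of other cells; MHC class II presentation, alternative activation, phagocytosis and scavenger receptors, matrix remodelling and proteases, glycolysis and HIF1 targets, oxidative phosphorylation, unfolded protein and integrated stress response, heat shock proteins, p53 targets and DNA damage, metallothioneins and iron handling, complement, glucocorticoid receptor targets, immediate early genes, and mitochondrially encoded genes. A response score per mouse was the mean log2 CPM of genes higher with ozone minus that of genes lower with ozone. Its ozone-minus-air difference in the 23 same-strain same-sex pairs given by the labels was compared between strains by a permutation test of the F ratio with 100000 resamples.

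Named genes followed a rule: across strains the 12 largest rises and 12 largest falls among called genes with the same sign in all 6 strains, a mean log2 CPM of at least 2 and a symbol that is not a clone or predicted name; in each strain the 4 largest rises and 4 largest falls by the same rule without the condition on signs; for differences between strains the 12 smallest p; for sex the 6 smallest p, with the X- and Y-linked genes that check sex labels; Nnt for strains in air; and members of the lists, up to 4 of the smallest p, with any member allowed where its list is described. Groups, tests, lists, this rule and the alternatives were chosen before the data were examined, except the following, which were added afterwards: leaving out the 3 libraries with the fewest detected genes, the number of detected genes as a covariate, leaving out Rn45s, gene lengths as an offset, single-gene tests of 1 strain's response against the mean of the others, and leaving out each mouse for the lists.

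The alternatives chosen beforehand were other scalings (the size factors of DESeq2 in edgeR, and library size alone), no filter and a stricter filter, DESeq2 1.42.0 and limma-voom as tools, no sex term, the replicate letter as a block, the mean of the neutrophil or epithelium markers per mouse as a covariate, a fit on the mice of 1 strain or on air mice alone, and leaving out each mouse. Work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

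The total count per library ran from 2407578 to 16632999 (median 6194997), of which Rn45s, the gene of the ribosomal RNA precursor, took 12.5 to 46.5% (median 25.6). The counts left for other genes were 1367468 to 13638798 (median 4632330). The median SE of a log2 fold change was 0.27 across strains and 0.63 to 0.73 within a strain. Reads carried no molecular identifiers in the tables, so floors cover counting error only, while SE and SD include the variation between mice. A fold against a group whose mice all had 0 counts is given as a lower bound, against a floor of 3 counts over the group. Replicates were separate mice. The 66 pairs of mice within groups had correlations of log2 CPM across genes of 0.718 to 0.979 and chi-square values per gene of 7.12 to 311, so none were the same library.

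The procedure was tested on simulated data with 200 genes changed by known folds, drawn with the means and library sizes of the real mice. Apart from the planted changes, each gene had 1 mean for all mice and was drawn independently. Simulated libraries thus lacked shifts shared by many genes, and their false calls do not bound those in the real mice. Across strains (11915 genes) it recovered 63.3, 86, 97.9 and 100% of genes changed 2, 4, 8 and 16-fold, with 12 false calls among 183. Within a strain of 4 pairs (11950 genes) it recovered 8, 38, 55.1 and 70.8%, with 4 false calls among 88, and with 3 pairs (11881 genes) 12.2, 40, 60.4 and 68.8%, with 1 among 89. A response that differed in 1 strain (11950 genes) was recovered in 0, 18, 44.9 and 54.2%, with 3 false calls among 60, and a difference of 1 strain in air (11907 genes) in 8.16, 40, 57.1 and 69.4%, with 1 among 87. Among 30 simulated lists, the list planted with changed genes reached an adjusted p of 1.09e-36 (camera) and 0 of the random lists were called. Because simulated genes were independent, this does not check calls at the preset correlation for lists whose members are correlated.

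Genes of multigene families (the Ear ribonucleases, Chil3 and Chil4, S100a8 and S100a9, keratins) can share reads, and the count of each is uncertain to that extent. Y-linked genes were listed only for C57BL/6J and were not tested. The 117 genes missing from some strains' tables were left out.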

Results

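Gene expression was measured in airway macrophages, the phagocytes of the airspaces, from 46 mice of 6 inbred strains. Mice breathed ozone at 2 ppm or filtered air during 3 hours, and cells were taken 21 hours later. C57BL/6J, CC017/Unc, CC025/GeniUnc, CC039/Unc and CC059/TauUnc had 4 air and 4 ozone mice each, and CC003/Unc had 3 of each. The labels gave an ozone and an air mouse of the same strain and sex the same letter, which made 23 pairs, but tied no letter to a litter, cage or day. The series names strain-dependent responses to ozone as its question. The comparisons were therefore ozone against air across strains and within each strain, the difference of that response between strains, strain differences in air, and sex.

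Xist, the RNA that silences an X chromosome in females, had 834 to 4730 CPM (relative to counts outside Rn45s) in female mice and 0 to 72.9 in male mice, so every library had the sex its label gives. Libraries held 2407578 to 16632999 counts, of which 12.5 to 46.5% came from Rn45s, the ribosomal RNA precursor. Counts of the compared genes were 7244893 ± 3378652 in ozone mice and 6321251 ± 3103245 in air mice (SD, n = 23 each; permutation p = 0.363, two-sided), and Rn45s shares were 24.2 ± 8.86% and 28.2 ± 9.50% (permutation p = 0.103). More genes reached 5 counts in ozone mice (10985 ± 709) than in air mice (10054 ± 924), in 19 of 23 pairs (permutation p = 2e-04). The air mice of pairs C and D of CC017/Unc and of pair C of CC059/TauUnc had the fewest detected genes.

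**Figure D1:**
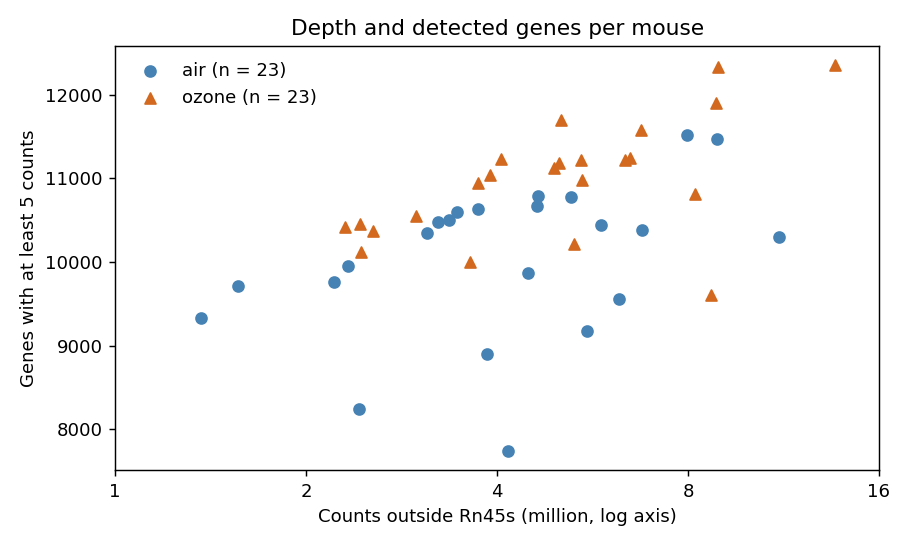
Genes with at least 5 counts (vertical axis) against counts outside Rn45s (horizontal log axis), 1 point per mouse, circles for air and triangles for ozone. Ozone libraries averaged 10985 detected genes and air libraries 10054.

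Genes were named across strains only if their change had the same sign in all 6 strains. Among such genes, the 12 largest rises with ozone included 5 of the epithelium markers, S100a9 and Sorl1 of the neutrophil markers, and Thbs1 and F13a1 of the monocyte markers. Rab15, a small GTPase of endosomes, rose from a mean of 0.170 to 9.55 CPM (log2 change 6.29 ± 0.54, SE), and Thbs1, the matrix protein thrombospondin 1, from 15.3 to 401 CPM (5.06 ± 0.44). Sorl1, a sorting receptor, rose from 4.47 to 24.5 CPM (3.84 ± 0.44). Among genes of epithelium, Scgb1a1, the secretory protein of club cells, went from 8.17 to 503.5 CPM (5.91 ± 0.57), and the keratins of simple epithelia Krt7 (5.20 ± 0.60), Krt18 (4.05 ± 0.57) and Krt8 (3.88 ± 0.43) and the tight junction gene Cldn4 (3.84 ± 0.57) rose with it. S100a9, a subunit of calprotectin abundant in neutrophils, rose from 2.31 to 39.7 CPM (5.51 ± 0.61). Cyp1b1, a cytochrome P450 (5.13 ± 0.58), F13a1, a subunit of coagulation factor XIII (4.75 ± 0.60), and Plbd1 (4.09 ± 0.58) completed the group, from air levels of 0.503, 0.589 and 0.558 CPM to 7.66, 8.34 and 10.6 CPM. Adjusted p of the 12 genes were 9.50e-12 for Rab15 to 3.33e-06 for Cldn4 (edgeR quasi-likelihood test, 23 mice per treatment). Fitted folds of Rab15, S100a9, Cyp1b1 and F13a1 depend on the prior count because some strains had 0 counts in air. The mean of a marker list as a covariate removes changes of its own members by construction, so those are left out here. With the epithelium markers 4 of the other 7 genes lost their call (median log2 change from 5.06 to 4.15, median SE from 0.58 to 0.98), and with the neutrophil markers 3 of the other 10 did (4.90 to 3.65, 0.57 to 0.86). Rab15 (4.68 and 4.86) and Thbs1 (4.06 and 3.80) passed with both, and Plbd1 (2.73 and 0.91) with neither. The monocyte markers were not used as a covariate.

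Among the largest falls by the same rule, Zfp36, which encodes the mRNA-destabilising protein tristetraprolin, fell from 619 to 174 CPM (-1.62 ± 0.21). Cd83, a surface marker of activated antigen-presenting cells, fell from 139.9 to 35.0 CPM (-1.94 ± 0.25). Mmp13, a collagenase, fell from 39.3 to 8.01 CPM (-2.10 ± 0.34), Tppp3 from 53.9 to 8.56 CPM (-2.68 ± 0.31) and Slc9a9, an endosomal sodium-proton exchanger, from 18.8 to 4.67 CPM (-2.20 ± 0.29). Abca9 (-2.38 ± 0.47), Dact2 (-2.18 ± 0.58), Treml4 (-1.83 ± 0.21), Cx3cl1, the chemokine fractalkine (-1.64 ± 0.36), Agmo (-1.58 ± 0.23), Patj (-1.55 ± 0.22) and the vitamin D receptor gene Vdr (-1.53 ± 0.36) completed the 12. Their adjusted p ran from 2.89e-09 for Treml4 to 0.00504 for Dact2. The fall of Vdr rested on a single library: without the CC017/Unc air mouse of pair C it was -0.68 (adjusted p = 0.109). Dact2 had 0 counts in the ozone mice of CC039/Unc, so its fold depends on the prior count. With the epithelium markers as a covariate 8 of the 12 lost their call and with the neutrophil markers 7, while Agmo, Cd83, Tppp3 and Treml4 passed with both. The median log2 change went from -1.88 to -2.07 and -1.70, and the median SE from 0.30 to 0.54 and 0.54.

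In all, 2278 of 12238 genes changed with ozone across strains, 1300 higher and 978 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), and 812 and 158 of them by more than 2-fold. The same sign was seen in all 6 strains for 749 higher and 505 lower genes. Scaling by library size alone moved the median of all genes from 0.06 to 0.28 log2 and gave 2404 higher and 370 lower genes, 86.7% higher against 57.1%. Markers of neutrophils and of epithelium were also higher in ozone mice: with the mean of the neutrophil markers as a covariate 178 genes were higher and 175 lower, with that of the epithelium markers 76 and 51, and with the number of detected genes, added after the data were seen, 656 and 624.

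**Figure D2:**
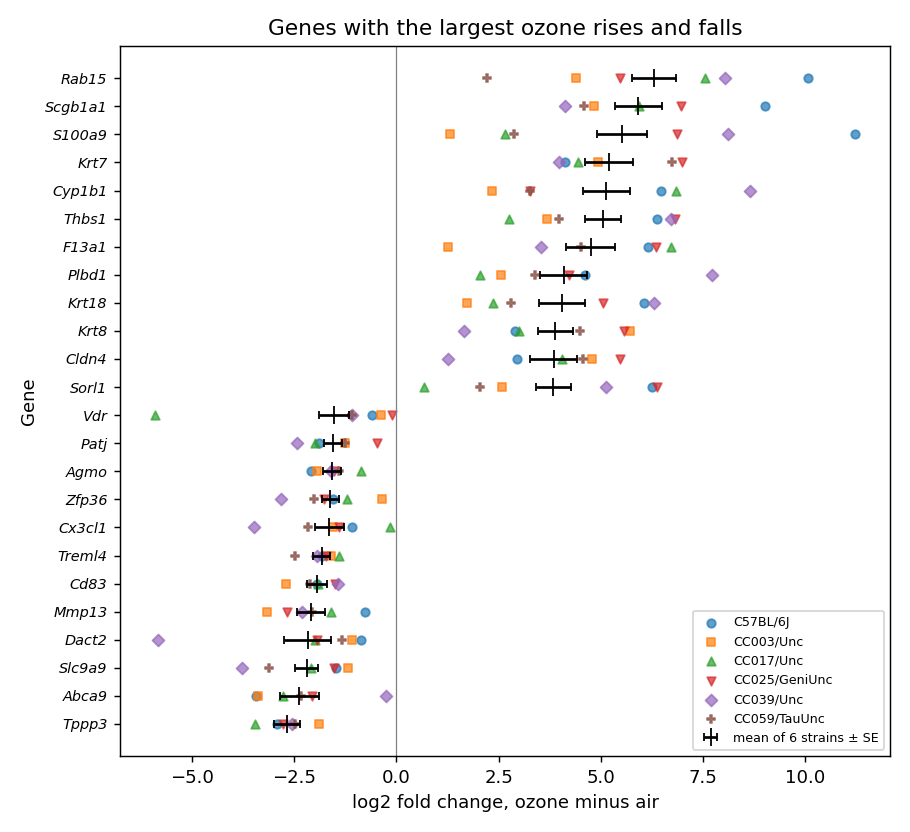
Log2 fold change of ozone against air (horizontal axis) for the 12 largest rises and 12 largest falls across strains, with coloured symbols for each strain and black bars for the mean of 6 strains ± SE. All symbols of a gene lie on the same side of 0 by selection, because only genes with the same sign in all 6 strains were named. The values of Rab15, S100a9, Cyp1b1 and F13a1 depend on the prior count where a strain had 0 counts in air.

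Genes of cell division formed the most uniform group. Of 48 cell cycle genes, 46 rose and 0 fell, over all genes tested and likewise adjusted over the list alone, with a median log2 change of 1.53. DNA replication genes were among them: Mcm3, a subunit of the replicative helicase, went from 36.5 to 103.5 CPM (1.52 ± 0.12) and Rrm1, of ribonucleotide reductase, from 30.9 to 119 CPM (1.97 ± 0.17). So did genes of mitosis and of cycling cells, with Top2a, topoisomerase II, rising from 74.7 to 225.5 CPM (1.67 ± 0.16) and Mki67, the Ki-67 antigen, by 2.14 ± 0.23. The list differed from other genes with an adjusted p of 4.14e-38 (camera), and the call held with an estimated correlation (adjusted p = 1.19e-04). Detected genes, neutrophil markers and epithelium markers moved with it: 44, 20 and 8 members passed with these as a covariate, at median changes of 1.49, 1.47 and 1.15.

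Immediate early genes, which respond first to stimulation, moved the other way. Of 24, 20 fell and 1 rose, 22 and 1 adjusted over the list alone (median -0.91; camera adjusted p = 1.06e-17, and 0.00793 with an estimated correlation). Dusp1, a MAP kinase phosphatase, fell to 219 CPM (-1.32 ± 0.13), Fosb from 179 to 60.8 CPM (-1.52 ± 0.21), Fos by 1.02 and Atf3 by 1.03 on the log2 scale. With the detected genes, the neutrophil markers and the epithelium markers as a covariate, 13, 4 and 2 members fell, at medians of -0.80, -0.68 and -0.51.

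**Figure D3:**
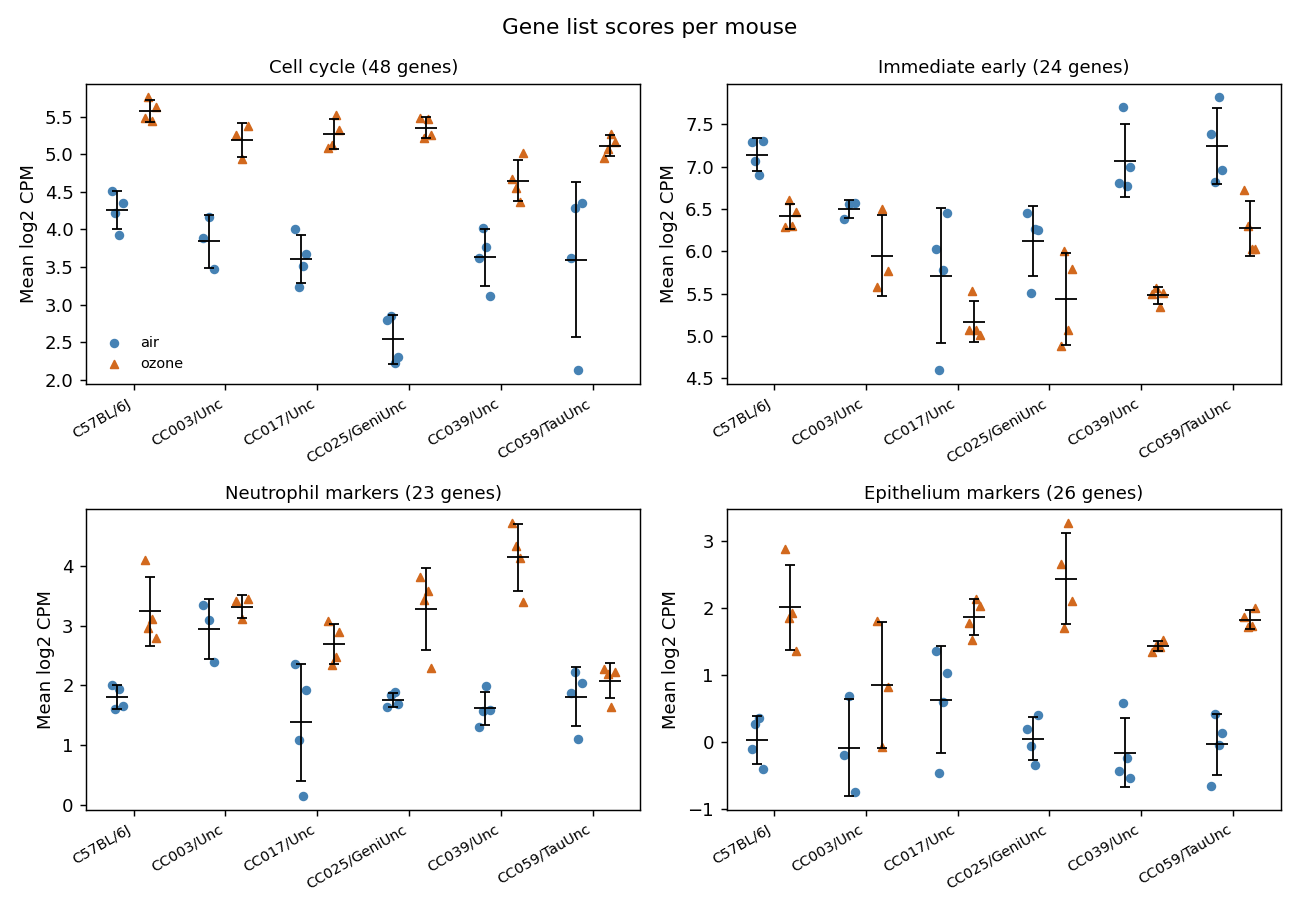
Mean log2 CPM of 4 gene lists per mouse by strain, circles for air and triangles for ozone, with bars for mean ± SD. Cell cycle scores were 2.13 to 4.52 in air and 4.37 to 5.76 with ozone, and epithelium scores -0.76 to 1.36 in air and -0.09 to 3.27 with ozone.

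Genes that mark macrophages of different origin were tested as 2 lists. Of 25 genes of resident alveolar macrophages, 10 fell and 4 rose, 13 and 4 adjusted over the list alone (median -0.40; camera adjusted p = 1.26e-04, and 0.00793 with an estimated correlation). The lipid droplet gene Cidec fell from 129 to 51.4 CPM (-1.43 ± 0.16), the surface lectin Siglecf from 257 to 153 CPM (-0.79 ± 0.11) and Fabp1 by 1.49 on the log2 scale, while the carbonic anhydrase Car4 rose from 437 to 670 CPM (0.73 ± 0.12). With library size alone 5 fell and 5 rose. Of 24 genes of recruited and monocyte-derived macrophages, 10 rose and 3 fell, 11 and 3 adjusted over the list alone (median 0.99; camera adjusted p = 0.00799). That call was lost with an estimated correlation (adjusted p = 0.130). Itgam, the integrin CD11b, rose from 5.57 to 65.8 CPM (3.55 ± 0.33), Spp1, osteopontin, from 1119 to 2686 CPM (1.23 ± 0.16), and Arg1, arginase 1, by 3.33 ± 0.57, while Cd14 and Csf1r were among those that fell. With the epithelium or the neutrophil markers as a covariate, 2 recruited-macrophage genes rose (medians 0.64 and 0.33) and 3 and 5 resident genes fell (medians -0.26 and -0.16).

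Markers of neutrophils and of epithelium were higher in the mean of the strains, but the lists did not pass against other genes in each strain. The neutrophil list did not pass in CC003/Unc (camera adjusted p = 0.316) or CC059/TauUnc (0.814, median 0.18), and the epithelium list did not in CC017/Unc (0.165). That is not absence of a rise: epithelium scores in CC017/Unc were 1.52 to 2.13 with ozone and -0.47 to 1.36 in air (mean log2 CPM). The neutrophil median was highest in CC039/Unc (3.05). Of 23 neutrophil genes, 11 rose and 4 fell, with the same counts adjusted over the list alone (median 1.57; camera adjusted p = 1.33e-05, and 0.0433 with an estimated correlation). The neutrophil antigen gene Cd177 rose from 0.108 to 4.70 CPM, the gelatinase gene Mmp9 from 1.27 to 9.51 CPM and Lcn2, lipocalin 2, from 0.442 to 3.79 CPM, while the formyl peptide receptor gene Fpr1 fell by 1.05 on the log2 scale. Of 26 genes of airway and alveolar epithelium, 16 rose and 0 fell, 18 and 1 adjusted over the list alone (median 2.35; camera adjusted p = 2.41e-10, and 0.00793 with an estimated correlation). Besides the genes named above, the club cell genes Cbr2 (3.25) and Cyp2f2 (2.67) and the surfactant protein gene Sftpb (3.55, with 0 counts in the air mice of 2 strains) rose. With the other list's markers as a covariate, 2 neutrophil and 3 epithelium genes rose (medians 0.17 and 1.09), and with the detected genes 9 and 12 did (1.49 and 2.00).

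A further 4 lists passed at the preset correlation and lost that call with an estimated correlation. Cytokine and chemokine genes were lower: 10 of 28 fell and 1 rose, 15 and 1 adjusted over the list alone (median -0.56; camera adjusted p = 4.87e-04; adjusted p = 0.195 with an estimated correlation). Ccl3 (-0.99 ± 0.14), Cxcl2 (-1.13 ± 0.24), Osm (-0.95) and Ccl2 fell, and Ptgs2, cyclooxygenase 2, rose (0.97 ± 0.26). Of 22 cholesterol synthesis genes, 8 rose and 0 fell on both counts (camera adjusted p = 0.00442; adjusted p = 0.330 with an estimated correlation), with Idi1 at 1.11 ± 0.17 and Fdps at 0.93. Of 19 glucocorticoid receptor targets, 9 fell and 3 rose, 11 and 4 adjusted over the list alone (camera adjusted p = 0.00442; adjusted p = 0.195 with an estimated correlation), among them Sgk1 (-0.75) and Dusp1. Of 34 oxidative phosphorylation genes, 7 rose and 0 fell on both counts, such as Ndufs1 (0.65 ± 0.14; camera adjusted p = 0.0222; adjusted p = 0.463 with an estimated correlation). With the epithelium markers as a covariate, 1 cytokine gene and 2 glucocorticoid targets fell, and 0 cholesterol genes and 1 oxidative phosphorylation gene rose (edgeR). The medians of these lists were -0.79, -0.20, 0.54 and 0.50 with it, and -0.56, -0.39, 0.40 and 0.24 without it. With the neutrophil markers, 6 cytokine genes and 4 glucocorticoid targets fell, and 1 cholesterol gene and 1 oxidative phosphorylation gene rose. With library size alone, 12 cholesterol and 19 oxidative phosphorylation genes rose and 5 glucocorticoid targets fell.

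The remaining lists did not pass with camera (adjusted p of 0.0585 or more, and 0.195 or more with an estimated correlation), although single members did. Some passed with fry. T and NK lymphocyte genes (fry adjusted p = 9.96e-04) and LXR targets (0.0338) were lower by it. Alternative activation (0.00188), glycolysis (0.00188), matrix (0.00242) and monocyte genes (0.00503) were higher by fry. NRF2 targets had 7 lower and 2 higher genes of 25, with Gstm1 at -1.04 ± 0.15, Hmox1 at -0.48 ± 0.15 and Gsta4 from 0.0363 to 1.13 CPM, with 0 counts in 21 of 23 air mice. Type I interferon genes had 3 lower and 2 higher of 31, LXR targets 7 lower and 3 higher of 30 (7 and 5 adjusted over the list alone), and MHC class II genes 3 lower and 1 higher of 13 (4 and 4). Monocyte genes split into 7 higher, such as S100a6 (3.64), and 7 lower, such as Lyz2 (-0.84), of 20. Alternative activation genes had 4 higher, such as Retnla (0.112 to 2.23 CPM, 0 counts in 21 of 23 air mice), and 4 lower, such as Cish (-1.36), of 21 (5 and 5). Matrix genes had 11 higher, such as Timp1 (3.60), and 7 lower, such as Plaur (-0.97), of 26. Glycolysis genes had 9 higher, such as Pgk1 (0.89), and 7 lower, such as Pfkfb3 (-0.76), of 28. Phagocytosis genes had 7 higher, such as Msr1 (0.99), and 5 lower, such as Axl (-0.62), of 24. Unfolded protein response genes had 6 in each direction of 26, or 10 higher and 6 lower adjusted over the list alone, and complement genes 5 higher and 4 lower of 18 (5 and 5). Heat shock genes had 3 higher and 0 lower of 15, p53 targets 0 higher and 3 lower of 22, and metallothionein and iron genes 3 higher and 4 lower of 20 (3 and 5). Where no count is added, that adjusted over the list alone was the same. Timp1 had 0 counts in the air mice of 1 strain, so its fold depends on the prior count. The balance of higher and lower members depended on scaling. With library size alone the counts were 12 higher and 1 lower for glycolysis, 7 and 1 for phagocytosis, 12 and 4 for the unfolded protein response, 3 and 2 for NRF2 targets, 6 and 4 for LXR targets, 4 and 2 for MHC class II, 5 and 1 for alternative activation, and 3 and 3 for p53 targets. With that scaling the type I interferon (adjusted p = 0.0174), T and NK lymphocyte (0.0258) and MHC class II (0.0442) lists passed as low relative to other genes (camera).

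Few markers of lymphocytes, eosinophils, and erythroid cells and platelets were measured. T and NK lymphocyte genes had 6 measured members, of which Cd2 fell (-1.51), B lymphocyte genes 2, of which Cd22 fell (-0.76), and eosinophil genes 2, of which Ltc4s fell (-0.75). Dendritic cell genes had 2 higher, such as Ciita (2.59, with 0 counts in the air mice of 2 strains), and 3 lower, such as Cd83, of 16 (3 and 4 adjusted over the list alone), and 0 of 2 erythroid and platelet genes were called. The mean change and the camera test differed in sign for NRF2 targets (median -0.10, mean 0.10), dendritic cells (0.54, 0.59), erythroid cells (0.50, 0.50), phagocytosis (-0.07, 0.27), the unfolded protein response (0.08, 0.02), p53 targets (0.02, 0.03), metallothioneins (-0.10, 0.06) and complement (0.05, 0.58), all lower by the test. With library size alone the medians of the NRF2 (0.12), interferon (0.03), LXR (0.18), phagocytosis (0.15) and metallothionein (0.07) lists turned positive.

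Within C57BL/6J, ozone raised genes that were near or at 0 counts in air. S100a9 had 0 counts in 4 air mice and 40.2 ± 39.1 CPM with ozone (SD, n = 4), at least 337-fold higher, Rab15 18.5 ± 20.1 CPM, at least 155-fold higher, and the chitinase-like gene Chil1 6.35 ± 4.16 CPM, at least 53.2-fold higher. Scgb1a1 went from 1.40 ± 0.484 to 734 ± 811 CPM (9.02 ± 1.55, SE). The largest falls were N4bp2l1 (-2.57 ± 0.64), the serotonin transporter gene Slc6a4 (-2.02 ± 0.42), the kinase gene Pim3 (-1.81 ± 0.44) and Gadd45g (-1.67 ± 0.38). Their adjusted p were 1.27e-04 for Rab15 to 0.0409 for N4bp2l1 (edgeR quasi-likelihood test). In all 73 genes changed, 53 higher and 20 lower, and a fit on the mice of this strain alone called 249. Without single mice the count was 32 (air, pair D), 26 (ozone, pair A), 30 (air, pair A), 44 (ozone, pair B) and 30 (air, pair C). S100a9, Rab15 and Scgb1a1 passed with each mouse left out; Slc6a4 was lost without the ozone mouse of pair A (adjusted p = 0.0519), and the highest adjusted p without a mouse were 0.172 for Chil1, 0.352 for N4bp2l1 and 0.139 for Pim3, each without the air mouse of pair A, and 0.103 for Gadd45g without the ozone mouse of pair A.

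In CC003/Unc, the strain with 3 pairs, 0 genes passed with edgeR, while 1031 had an unadjusted p under 0.05; DESeq2 called 80 genes and limma-voom 42. Without the ozone mouse of pair B edgeR called 3. Cell cycle genes were still higher there as a list (24 of 48 adjusted over the list alone, 0 over all genes; camera adjusted p = 2.10e-23, and 0.00409 with an estimated correlation).

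In CC017/Unc, S100a6, a calcium-binding protein, rose from 1 count in 4 air mice (0.138 CPM) to 10.7 ± 3.64 CPM, and Cyp1b1 from 1 count (0.0840 CPM) to 8.64 ± 6.89 CPM. Rab15 and F13a1 had 0 counts in air and were at least 15.7-fold and 10.1-fold higher with ozone. Apoe, apolipoprotein E, fell from 64.2 ± 71.1 to 8.82 ± 10.5 CPM (-2.95 ± 0.85), Tppp3 by 3.46 and Grcc10 by 2.96 on the log2 scale, and Vdr by 5.90 (± 1.15). The adjusted p of the 8 genes were 0.00353 for S100a6 to 0.0446 for Apoe. The fit called 424 genes, 248 higher and 176 lower, but a fit on the mice of this strain alone called 0 (edgeR, 786 at an unadjusted p under 0.05), and 3 of the 34 other splits of these mice called more than 424, up to 562. The count was 67 without the ozone mouse of pair A, 60 without that of pair B, 1244 without that of pair C, and 242 and 241 without the air mice of pairs C and D. The call of Vdr was lost without the air mouse of pair C (-0.89, adjusted p = 0.735), which held 46.2 CPM. Rab15 and S100a6 passed with each mouse left out; without the ozone mouse of pair A adjusted p was 0.228 for F13a1, 0.0966 for Grcc10 and 0.0689 for Tppp3, without that of pair B 0.0616 for Cyp1b1, and without the air mouse of pair D 0.248 for Apoe.

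In CC025/GeniUnc, Scgb1a1 rose from 8.01 to 1024 ± 805 CPM (6.96 ± 1.35, SE), Krt7 from 0.211 to 29.5 ± 16.8 CPM (6.99 ± 1.45), S100a9 from 0.247 to 24.8 ± 22.9 CPM and Thbs1 by 6.81 ± 1.14. The caveolae gene Cav1 fell (-1.89 ± 0.36), as did complement component C3 (-1.81 ± 0.38), Tppp3 (-2.76 ± 0.74) and Zfp36 (-1.76 ± 0.50). Adjusted p were 4.39e-04 for Thbs1 to 0.0457 for Zfp36. A total of 293 genes changed, 225 higher and 68 lower, and a fit on the mice of this strain alone called 506. The count was 164 and 148 without the ozone mice of pairs A and B, and 130, 163 and 147 without the air mice of pairs B, C and D. All but Tppp3 (highest adjusted p 0.133, without the ozone mouse of pair A) and Zfp36 (0.173, without that of pair B) passed with each mouse left out.

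In CC039/Unc, Arg1 rose from 0.215 ± 0.280 to 175 ± 116 CPM (9.54 ± 1.69) and S100a9 from 0.403 to 131 ± 95.8 CPM (8.12 ± 1.40). Cyp1b1 had 0 counts in air and 7.52 ± 7.24 CPM with ozone, at least 84.1-fold higher, and Rab15 rose from 1 count to 12.2 ± 8.14 CPM. Slc9a9 (-3.78 ± 0.74), Fosb (-3.50 ± 0.53), Cx3cl1 (-3.47 ± 0.92) and Mamdc2 (-3.09 ± 0.81) fell. Adjusted p were 1.29e-04 for Rab15 and Fosb to 0.0272 for Cx3cl1. A total of 319 genes changed, 155 higher and 164 lower, and a fit on the mice of this strain alone called 125. The count was 117, 126 and 143 without the ozone mice of pairs B, C and D, and 90 and 122 without the air mice of pairs B and D. Only Cx3cl1 and Mamdc2 among the 8 were lost without a mouse (highest adjusted p 0.106 without the ozone mouse of pair B and 0.0998 without that of pair C).

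In CC059/TauUnc, a pair of ribonuclease genes nearly vanished: Ear10 fell from 92.4 ± 101 to 0.265 ± 0.373 CPM (-8.48 ± 1.29) and Ang3 from 97.7 ± 82.3 CPM to 1 count in 4 ozone mice. Reads of Ear10 and Ang3 can be shared with close paralogs, and Ear10 had 0 counts in 1 of 4 air mice and in 2 of 4 ozone mice. Pianp fell from 5.34 CPM to 0 counts, at least 32.1-fold lower, and Slc9a9 by 3.11 on the log2 scale. Krt7 rose from 2 counts in air (0.106 CPM) to 13.9 ± 6.09 CPM, Krt8 by 4.48 ± 1.08, Thbs1 by 3.98 ± 0.96, and F3, tissue factor, by 4.60 on the log2 scale. Adjusted p were 1.72e-04 for Ear10 to 0.0490 for F3. The fit called 89 genes, 48 higher and 41 lower, but a fit on the mice of this strain alone called 0 (edgeR, 730 at an unadjusted p under 0.05), and 1 of the 34 other splits of these mice called 236. The count was 53, 43 and 44 without the ozone mice of pairs B, C and D, and 56 without the air mouse of pair C. Ear10 and Ang3 passed with each mouse left out; without the air mouse of pair C adjusted p was 0.424 for Pianp, 0.0965 for Slc9a9, 0.0693 for Krt7, 0.155 for F3 and 0.122 for Thbs1, and without that of pair A 0.104 for Krt8.

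Cell cycle genes were higher in every strain by the list test, with adjusted p from 1.94e-58 in CC025/GeniUnc to 3.44e-08 in CC039/Unc (camera). With an estimated correlation adjusted p were 0.00782 in C57BL/6J, 0.00409 in CC003/Unc, 2.38e-06 in CC025/GeniUnc and 0.0180 in CC059/TauUnc, and the call was lost in CC017/Unc (adjusted p = 0.198) and CC039/Unc (0.0726). The members that rose over all genes, and adjusted over the list alone, were 7 and 22 in C57BL/6J, 13 and 26 in CC017/Unc, 34 and 46 in CC025/GeniUnc, 6 and 11 in CC039/Unc, and 4 and 16 in CC059/TauUnc. Immediate early genes were lower in every strain at the preset correlation, and only in CC039/Unc with an estimated correlation (13 of 24 fell, 19 adjusted over the list alone; adjusted p = 2.29e-21, and 0.00487 estimated; estimated values in the others were 0.0645 to 0.620). Epithelium genes held with both settings in C57BL/6J, CC025/GeniUnc and CC059/TauUnc (1, 5 and 3 of 26 rose, 8, 10 and 8 adjusted over the list alone; estimated adjusted p = 0.00782, 0.00563 and 0.0351). Neutrophil genes did so in CC039/Unc (10 of 23 rose, 13 adjusted over the list alone; estimated adjusted p = 0.00122). In CC039/Unc cholesterol synthesis (4 of 22 rose, 14 adjusted over the list alone; estimated adjusted p = 0.0261), recruited macrophages and alternative activation were also higher and LXR targets lower with both settings. The same was true of recruited macrophages (higher) and MHC class II (lower) in C57BL/6J and of resident macrophages (lower) in CC025/GeniUnc. In all, 55 of 174 list tests within strains passed at the preset correlation and 16 with an estimated correlation.

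The response score, the genes raised minus those lowered across strains, was higher in the ozone mouse of all 23 pairs, which is no independent evidence because the genes were chosen on the same mice. It was 2.30 ± 0.41 in CC025/GeniUnc, 2.21 ± 0.19 in CC017/Unc, 1.99 ± 0.47 in CC039/Unc, 1.89 ± 0.82 in CC059/TauUnc, 1.75 ± 0.50 in C57BL/6J (log2, SD, n = 4 pairs each) and 1.11 ± 0.45 in CC003/Unc (n = 3). The difference between strains did not pass the planned test (F = 2.31, permutation p = 0.0908). With the raised genes alone p was 0.0318, against the mean of each strain's air mice, which leaves the spread of the air mice out of the error and makes p too small, 0.00318, and without the CC059/TauUnc pair C 0.0115 (permutation tests).

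**Figure D4:**
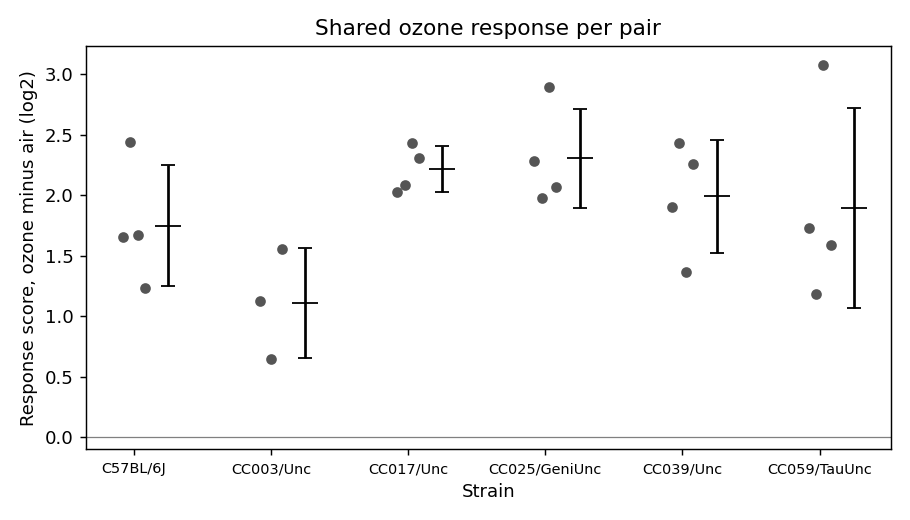
Ozone-minus-air difference of the response score (log2, vertical axis) per pair, by strain, with mean ± SD beside the points. All 23 values lie above 0, and CC003/Unc has the lowest mean (1.11).

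The response of 10 genes differed between strains (F test of the interaction, edgeR quasi-likelihood, Benjamini-Hochberg; 1329 genes at an unadjusted p under 0.05). Ear10 (adjusted p = 0.00740) fell in CC059/TauUnc, where its air level was 92.4 CPM, and was at 0.0619 to 5.35 CPM in air elsewhere. Chil3, a chitinase-like protein abundant in alveolar macrophages (adjusted p = 0.0293), rose in CC039/Unc (1.53 ± 0.32) and CC059/TauUnc (1.87 ± 0.33), the strains with the lowest air levels, and had values of -0.38 to 0.18 elsewhere. The other 8 had an adjusted p of 0.0417. Chst11, a chondroitin sulfotransferase, rose in C57BL/6J from 0.644 to 22.8 CPM (5.23 ± 0.79), against air levels of 6.65 to 47.8 CPM in the other strains, and its response was lower in CC025/GeniUnc (difference -5.45 ± 0.98, adjusted p = 0.0136) and CC059/TauUnc (-5.18 ± 0.98, adjusted p = 0.0175). Vcan, the proteoglycan versican, rose in CC039/Unc from 0.293 to 43.3 CPM (7.05 ± 1.14), as did the chemokine gene Ccl9 (2.85 ± 0.53). Kif20a, a mitotic kinesin, rose in CC025/GeniUnc (3.61 ± 0.50) from an air level of 3.73 CPM, against 11.9 to 29.4 CPM in air in other strains. Slc7a11, the cystine transporter, rose in CC017/Unc (1.39 ± 0.35) and fell in CC025/GeniUnc (-1.35 ± 0.35). The actin crosslinker Flna rose in C57BL/6J (1.13 ± 0.26) and CC059/TauUnc (1.35 ± 0.26), where the selenoprotein gene Sepp1 fell (-0.93 ± 0.23 and -1.31 ± 0.23). Cd53 rose in CC017/Unc (1.05 ± 0.26) and CC039/Unc (0.92 ± 0.26). Without a call in CC003/Unc, Cd53 stood there at -0.95 ± 0.30 and Sepp1 at -0.90 ± 0.27.

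**Figure D5:**
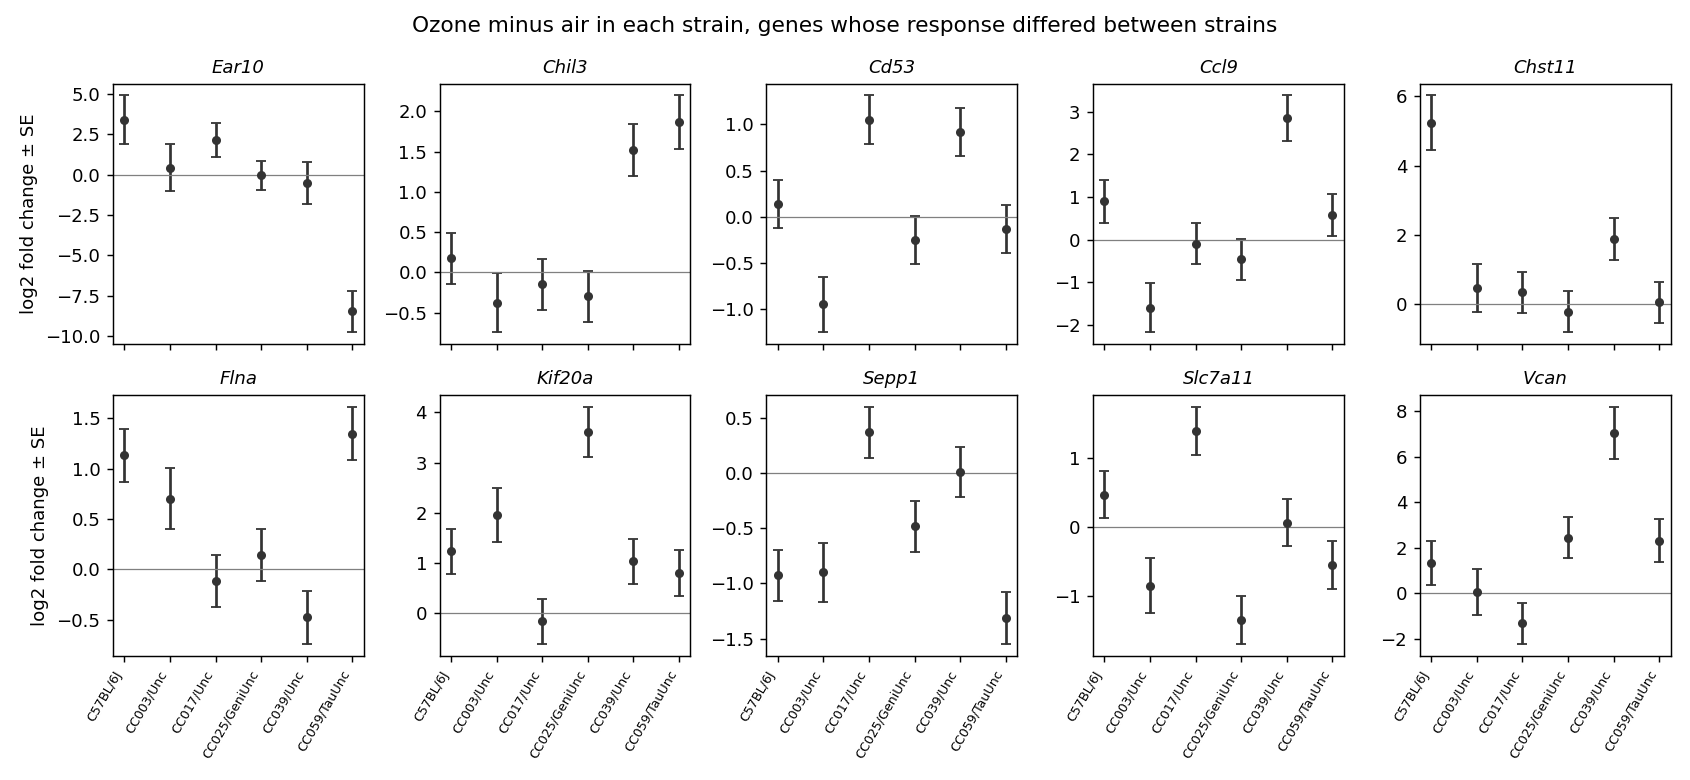
Log2 fold change of ozone against air ± SE in each of 6 strains for the 10 genes whose response differed between strains, each panel with its own vertical axis. Ear10 stands at -8.48 in CC059/TauUnc, Vcan at 7.05 in CC039/Unc and Chst11 at 5.23 in C57BL/6J.

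The count of 10 depended on single libraries. It was 0 without the CC059/TauUnc air mouse of pair D or ozone mouse of pair C (1317 and 1214 genes at an unadjusted p under 0.05, edgeR), and 1 without the CC003/Unc air or ozone mouse of pair A, the CC025/GeniUnc ozone mouse of pair A or the CC025/GeniUnc air mouse of pair B. It was 2 without the CC017/Unc ozone mouse of pair B, the CC025/GeniUnc ozone mice of pairs C and D, the CC039/Unc ozone mice of pairs B and C or air mouse of pair C, the CC059/TauUnc air mouse of pair B, or the C57BL/6J air mice of pairs C and D or ozone mouse of pair A. It was 3 without the CC003/Unc air mouse of pair B, the CC017/Unc ozone mouse of pair A, the CC025/GeniUnc ozone mouse of pair B or air mouse of pair D, the CC039/Unc air mouse of pair D, the CC059/TauUnc ozone mouse of pair A or the C57BL/6J air mouse of pair A. It was 4 without the CC003/Unc ozone mouse of pair D, the C57BL/6J ozone mouse of pair B, C or D, or the C57BL/6J air mouse of pair B, 5 without the CC025/GeniUnc air mouse of pair C, and 6 without the CC039/Unc air mouse of pair B. It was 16 without the CC039/Unc air mouse of pair A, 19 without the CC059/TauUnc air mouse of pair C and 130 without the CC017/Unc ozone mouse of pair C. DESeq2 called 179 genes and limma-voom 47. Tested singly against C57BL/6J, the responses of CC003/Unc, CC017/Unc and CC039/Unc differed in 0 genes (728, 839 and 769 at an unadjusted p under 0.05, edgeR), that of CC025/GeniUnc in Chst11, and that of CC059/TauUnc in Chst11 and Ear10.

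As lists, responses of a strain were tested against the mean of the other 5. Cell cycle genes rose more in CC025/GeniUnc (median difference 1.42; 25 of 48 higher adjusted over the list alone, 0 over all genes; camera adjusted p = 2.92e-31, and 5.62e-04 with an estimated correlation). In CC039/Unc the responses of neutrophil genes (median difference 1.77; adjusted p = 2.52e-11, estimated 0.00317), cholesterol synthesis (0.90; 5.77e-08, estimated 0.0494), alternative activation (0.81; 1.5e-04, estimated 0.00317) and MHC class II genes (1.26; 7.13e-04, estimated 0.0494) were higher. That of LXR targets was lower there (-0.47; 0.00629, estimated 0.0494). These 6 of 174 list differences held with both settings, and 37 passed at the preset correlation. The same air mice enter this comparison and that of strains in air, in which cell cycle genes were lower in CC025/GeniUnc and MHC class II and alternative activation genes lower in CC039/Unc.

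In filtered air, 2880 genes differed between strains, and 1524 with a fit on air mice alone, 1510 of them shared. Chil3 (F test adjusted p = 1.26e-13) had 9219 ± 1594 CPM in C57BL/6J, 14240 in CC025/GeniUnc, 2161 in CC039/Unc and 406 ± 269 in CC059/TauUnc (SD, n = 4). Awat1, an acyltransferase of wax synthesis, had 75.8 CPM in CC017/Unc, 62.8 in CC025/GeniUnc, 2.95 in C57BL/6J and 0.542 in CC003/Unc. Flt1, a receptor of vascular endothelial growth factor, had 119 ± 19.1 CPM in C57BL/6J, 1.63 in CC003/Unc and 3.11 in CC059/TauUnc, and the nuclear receptor corepressor Nrip1 90.7 CPM in C57BL/6J and 0.9995 in CC059/TauUnc (-6.39 ± 0.52). Against C57BL/6J, Ctnna1, an adherens junction gene, was higher in CC003/Unc (2.65 ± 0.26), Ptgr1 in CC025/GeniUnc (3.90 ± 0.43) and CC039/Unc (2.28 ± 0.41), and the proton pump gene Atp6v0a1 in CC025/GeniUnc (1.84 ± 0.25) and CC039/Unc (1.51 ± 0.25). Pdk4, a pyruvate dehydrogenase kinase, was higher in CC017/Unc (3.18 ± 0.43), Fabp4, a fatty acid carrier, in CC003/Unc (3.38) and CC017/Unc (2.85), and Alas1, of haem synthesis, higher in CC025/GeniUnc (1.30) and lower in CC059/TauUnc (-1.31). Cd24a was lower in CC017/Unc (-2.84 ± 0.35), and Tgfbi was lower in each of the 5 strains, by 1.26 to 2.78 on the log2 scale, with the same 4 C57BL/6J mice as the reference. The adjusted p of these 12 genes were 1.26e-13 to 4.28e-11 (edgeR quasi-likelihood F test).

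Nnt, part of which is deleted in C57BL/6J, also passed (adjusted p = 0.0188), with 13.2 ± 7.38 CPM in C57BL/6J, 6.70 in CC059/TauUnc and 38.8 in CC039/Unc, but in 0 of the 5 single contrasts; it was lost without the CC039/Unc air mouse of pair C (0.0509), without the CC059/TauUnc air mouse of pair A (0.0514), and with air mice alone (0.169). Against C57BL/6J, 1319 genes differed in CC025/GeniUnc (772 higher, 547 lower), 855 in CC039/Unc (502, 353), 592 in CC017/Unc (309, 283), 334 in CC003/Unc (221, 113) and 155 in CC059/TauUnc (79, 76). These comparisons share the C57BL/6J air mice, so their counts are not independent. Transcript lengths in the deposited tables differed between strains, and of 388 genes whose effective length differed between libraries by over 0.25 log2, 26.3% were called, against 23.4% of the other 11850. Whether each strain's reads were quantified against its own sequence is not given in the sources used here. Reads lost where a strain's sequence differs from the reference could also lower a gene's count, which was not tested.

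MHC class II genes were lower than in C57BL/6J in the air mice of CC003/Unc (4 of 13, 6 adjusted over the list alone; camera adjusted p = 1.46e-05, estimated 0.0242), CC025/GeniUnc (6 of 13 lower and 1 higher on both counts; 3.93e-05, estimated 0.0217) and CC039/Unc (5 of 13, 6 adjusted over the list alone; 6.00e-06, estimated 0.0128). In CC017/Unc and CC059/TauUnc the list passed at the preset correlation (0.00307 and 0.00377) and was lost with an estimated correlation (adjusted p = 0.297 and 0.203). Reads of these genes lost to sequence differences between strains were not told apart from lower expression. Cell cycle genes were lower in CC025/GeniUnc (20 of 48, 35 adjusted over the list alone; 2.30e-16, estimated 0.0217) and alternative activation genes in CC039/Unc (3 of 21 on both counts; 0.00458, estimated 0.0190). Lists of 2 genes passed in CC025/GeniUnc (B lymphocytes, estimated 0.0428) and CC039/Unc (eosinophils, estimated 0.0412). Cholesterol synthesis genes were lower in CC003/Unc (3 of 22, 7 adjusted over the list alone; 6.25e-09, estimated 0.0586), CC017/Unc (6 of 22; 8.47e-05, estimated 0.297) and CC039/Unc (2 of 22; 0.00704, estimated 0.387), each lost with the estimated correlation.

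Between the sexes 2 genes differed, both higher in females: Xist (-7.21 ± 0.51, male minus female, adjusted p = 1.27e-11) and Tsix, its antisense gene, which lies below the level asked of named genes and was chosen after its values were seen (-5.87 ± 0.86, adjusted p = 9.50e-05). Without the CC059/TauUnc air mouse of pair C the count was 4. The ozone response differed between the sexes in 0 genes with edgeR (269 at an unadjusted p under 0.05), with DESeq2 (411) and with limma-voom (392).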

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

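The tests with the number of detected genes, and the choice of measures screened for libraries standing apart, came after the ozone results had been seen; the list of strain differences kept only lists that pass at both correlation settings, a criterion also set afterwards. Of 75 combinations of a measure with a group of mice or pairs screened for a value far from the others, 4 had such a value, and chance gives about 5 per 100. The CC025/GeniUnc ozone mouse of pair A had 5903258 counts against 10234205 to 11097646 in the other 3. The CC059/TauUnc air mouse of pair C had 41.7% of its counts in Rn45s against 26.4 to 28.9%. The neutrophil score of the CC059/TauUnc ozone mouse of pair C was 1.64 against 2.18 to 2.27 (mean log2 CPM). The immediate early score of the CC017/Unc ozone mouse of pair C was 5.53 against 5.01 to 5.07.

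The ozone response differed between strains by the interaction test for Ear10 (adjusted p = 0.00740), Chil3 (0.0293), and Ccl9, Cd53, Chst11, Flna, Kif20a, Sepp1, Slc7a11 and Vcan (0.0417 each; edgeR quasi-likelihood). By the list test it differed in CC025/GeniUnc for cell cycle genes (adjusted p = 2.92e-31), and in CC039/Unc for neutrophil genes (2.52e-11), cholesterol synthesis (5.77e-08), alternative activation (1.5e-04), MHC class II (7.13e-04) and LXR targets (0.00629).

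Outside the genes compared, 12 of the 117 genes listed for C57BL/6J but not for all Collaborative Cross strains had at least 5 counts in each of 8 C57BL/6J libraries. The cholesterol synthesis gene Hmgcs1 had 154 CPM there, Brox 84.4, Aida 55.7 and Mia3 51.8, with no entry for the 38 mice of the other strains. Had the gaps been read as counts of 0, 23 of these genes would have entered the test and 22 of them would have been called different between strains in air.

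The rise of cell cycle genes with ozone was 1.61 ± 0.117 as a mean list score (log2, SE). Fewer detected genes in the air libraries would remove the rise once they are accounted for, but it was 1.40 ± 0.130 with the number of detected genes as a covariate, which argues against them as the whole cause. Beside the neutrophil markers the rise was 1.33 ± 0.215, so the mean of these markers did not account for most of the rise. That mean is an imperfect measure of neutrophil content (11 of 23 markers rose and 4 fell), so neutrophils in the ozone samples are not excluded. RNA or cells of the epithelium stay open: beside the epithelium markers the rise was 1.18 ± 0.230, not clearly above 0.807, the level below which most of the rise would have gone. Division of macrophages after exposure, which the design would allow, may also contribute and was not tested.

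The rise of epithelium genes was 1.67 ± 0.161, and 1.41 ± 0.183 with the number of detected genes as a covariate, which argues against fewer detected genes in air as the whole cause (comparison level 0.833). If RNA or cells of the epithelium entered the ozone samples in varying amounts, its markers should vary together between ozone mice of a strain. Their median pairwise correlation over 23 ozone mice was 0.141, against a median of 0.0381 and a 95th percentile of 0.113 for random lists (128 of 10000 as large), which is consistent with such an admixture. The labels name no sort that would remove epithelial cells, Scgb1a1 reached 503.5 CPM, and expression of these genes by macrophages after ozone was not tested.

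Ear10 and Chil3 belong to families of close paralogs, so a strain's variants could shift reads between members without a change in their sum. For the sum of 9 Ear genes the difference between strains gave an adjusted p of 0.364, but Ear2 had 1536 CPM in the air mice of CC059/TauUnc against 92.4 for Ear10, so the sum says little of Ear10 and the explanation stays open for it. For the sum of Chil3 and Chil4 the adjusted p was 0.0335, with rises of 1.53 ± 0.32 in CC039/Unc and 1.85 ± 0.33 in CC059/TauUnc. That argues against a shift of reads between the 2 genes that leaves their sum unchanged. A change of Chil4 whose reads were counted as Chil3 would also change the sum, so it is not excluded. A response that depends on strain, as the design would allow, remains an untested hypothesis for both.

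Regrouping the mice at random tested whether chance can be excluded. It can for ozone across strains (2278 genes, highest of the other splits 2, 1 of 100 splits as large), strain differences in air (2880, 671, 1 of 100) and sex (2, 1, 1 of 50). The share was also under 0.05 for ozone in C57BL/6J (73, 1, 1 of 35), CC025/GeniUnc (293, 0, 1 of 35) and CC039/Unc (319, 9, 1 of 35). That is the smallest share that 35 splits allow, and no allowance was made for testing 6 strains. Chance is therefore not firmly excluded in these 3 strains taken singly. For the interaction, 3 of 100 splits were as large as the real one (10 genes). These splits cannot decide it, because mixing the treatments within strains also removes the ozone effect that strains share. Other splits called 171 and 159 genes, which points to some structure of the samples, and what it is was not tested. Chance cannot be excluded for CC017/Unc (424 genes, highest other 562, 4 of 35) or CC059/TauUnc (89 genes, highest other 236, 2 of 35). For the sex-by-ozone term the real count was 0, so that 50 of 50 splits had to reach it and the test decides nothing (highest other 41). In CC003/Unc the 10 splits are too few for a share under 0.05 (real value 0, highest other 0).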

How the results depend on the processing

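The runs with the number of detected genes, without the 3 libraries with the fewest detected genes, without Rn45s, with length offsets, and the leave-outs of the lists were added after the results had been seen; the others were planned. No named gene and no list that passed reversed its direction, except as stated next. Among the 10 lists that passed, medians changed sign only where the covariate was the mean of the list itself, which removes its change by construction (epithelium from 2.35 to -0.51, neutrophils from 1.57 to -0.30). Medians of lists that did not pass changed sign in several settings, and with library size alone NRF2 targets, LXR targets and MHC class II genes went from more members lower to more higher (7 and 2 to 2 and 3, 7 and 3 to 4 and 6, 3 and 1 to 2 and 4), as did interferon, dendritic cell and metallothionein and iron genes. The rises and falls across strains stayed within 1.5 times of 1300 and 978 under the size factors of DESeq2, both filters, DESeq2, limma-voom, no sex term, and without Rn45s or the 3 libraries. The count in air did so under all alternatives run for it but air mice alone, with 1524 genes, 1510 of them among the 2880. The cause of the following changes was not tested, except that a fit on the mice of a strain or on air mice alone uses fewer mice by construction.

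Library size alone gave 2404 higher and 370 lower genes across strains, 6 for the interaction, 222 in C57BL/6J, 269 in CC017/Unc and 212 in CC039/Unc; the size factors of DESeq2 gave 6 for the interaction. With no filter there were 451 for the interaction, 11 for sex, 6 for sex by ozone, and 177 in C57BL/6J, 139 in CC003/Unc, 682 in CC017/Unc, 534 in CC025/GeniUnc, 539 in CC039/Unc and 306 in CC059/TauUnc; a stricter filter gave 1 for sex. DESeq2 called 179 for the interaction, and in the same order of strains 214, 80, 1095, 552, 644 and 325; limma-voom called 47, and 197, 42, 857, 684, 576 and 57. The neutrophil markers as a covariate gave 178 higher and 175 lower genes across strains (150 and 119 shared with the fit without it), 15 in C57BL/6J, 4 in CC003/Unc, 8 in CC017/Unc, 138 in CC025/GeniUnc and 2 in CC039/Unc. The epithelium markers gave 76 and 51 (66 and 43 shared), 18 in C57BL/6J, 20 in CC017/Unc, 12 in CC025/GeniUnc, 57 in CC039/Unc and 43 in CC059/TauUnc. The number of detected genes gave 656 and 624 (617 and 470 shared), 4 in CC003/Unc, 33 in CC017/Unc and 180 in CC025/GeniUnc. Without the 3 libraries there were 28 for the interaction (7 shared), 4 for sex, 182 in C57BL/6J, 63 in CC003/Unc, 93 in CC017/Unc, 633 in CC025/GeniUnc and 861 in CC039/Unc. A fit on the mice of a strain alone gave 249 in C57BL/6J, 506 in CC025/GeniUnc, 125 in CC039/Unc, and 0 in CC017/Unc and CC059/TauUnc (edgeR; 786 genes and 730 at an unadjusted p under 0.05). Of the 29 lists across strains 10 passed with camera, 5 with an estimated correlation and 16 with fry; of those within strains 55, 16 and 41. The response score gave p = 0.0318 with raised genes alone and 0.00318 against the mean of the air mice, which leaves the spread of the air mice out of the error and makes p too small (permutation tests). Of the 24 genes named across strains, 17 lost their call with the epithelium markers and 12 with the neutrophil markers as a covariate; all 24 kept their sign. These include 5 epithelium markers and 2 neutrophil markers (S100a9 and Sorl1) that lost it with their own list, which is by construction. The median log2 change of the other rises went from 5.06 to 4.15 (7 genes) and from 4.90 to 3.65 (10 genes), and that of the 12 falls from -1.88 to -2.07 and -1.70, while the median SE went from 0.58 to 0.98 and 0.57 to 0.86, and from 0.30 to 0.54 and 0.54.

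Leaving out each mouse gave 1113 to 1462 higher and 782 to 1102 lower genes across strains, 0 to 130 for the interaction, 2403 to 3125 in air, 2 to 4 for sex, 0 to 0 for sex by ozone, 26 to 64 in C57BL/6J, 0 to 3 in CC003/Unc, 60 to 1244 in CC017/Unc, 130 to 260 in CC025/GeniUnc, 90 to 352 in CC039/Unc, 43 to 126 in CC059/TauUnc, 9 to 12 lists, and p = 0.0115 to 0.309 for the score (permutation tests). The interaction count was 0 without the CC059/TauUnc air mouse of pair D or ozone mouse of pair C (1317 and 1214 at an unadjusted p under 0.05, edgeR), against 179 with DESeq2 and 47 with limma-voom on all mice.

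The values did not settle whether the replicate letters pair the mice. Deviations of the mice of a pair from their groups correlated over 0.1 in 4 of 23 pairs. Their mean was 0.0411, against -0.0117 for the other ozone and air mice of a strain. The own pair was highest, among 3 or 4 air mice, in 10 of 23. Both lean toward pairing but were not tested, and mice of a pair also share a sex. With sex removed, more of the pairs had correlations below 0. Values then ran from -0.178 (C57BL/6J pair C) to 0.308 (CC059/TauUnc pair D), against -0.127 to 0.275 before. The letter as a replicate block gave 10 genes in CC003/Unc, 173 in CC039/Unc, 1155 higher and 777 lower across strains, and 10 for the interaction, 4 of them shared; it moved no other count of ozone genes by over 1.5 times. At 1367468 to 13638798 counts outside Rn45s and 3 or 4 mice per group, 8% of 2-fold changes within a strain of 4 pairs and 12.2% within that of 3 pairs were recovered in simulated data, so most changes of that size were not detectable within a strain.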

Other observations

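The single-gene test of a strain's response against the mean of the other 5 strains was added after the data were seen, and the genes named here follow from it. In CC017/Unc, the log2 change with ozone was higher than the mean of the others in 8 genes: Slc40a1, the iron exporter ferroportin (difference 4.55 ± 0.93, log2, SE), Cat, catalase (1.76 ± 0.36), the scavenger receptor Cd36 (1.49 ± 0.31), the cystine transporter Slc7a11 (1.83 ± 0.39) and the transcription factor Klf6 (1.40 ± 0.28), with Coro2b (4.55 ± 0.93), Fndc3a (1.27 ± 0.27) and Lrrc58 (1.14 ± 0.25). Their adjusted p were 0.0338, and 0.0447 for Lrrc58 (edgeR quasi-likelihood test). These values rest on few mice, and no mouse was left out in turn for this test. For ozone within CC017/Unc, the count moved from 424 to 1244 without the ozone mouse of pair C. A fit on the mice of that strain alone called 0 genes, and chance could not be excluded there (4 of 35 splits as large). The air mice of pairs C and D were among the 3 libraries with the fewest detected genes.

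In CC039/Unc, 6 genes responded differently from the mean of the others. Cd86, a costimulatory receptor (3.45 ± 0.70, adjusted p = 0.0309), Ccl9 (2.98 ± 0.57, 0.0213), Vcan (6.08 ± 1.14, 0.0160) and Emb (3.37 ± 0.71, 0.0425) had a higher log2 change, and Fos (-1.79 ± 0.37, 0.0350) and the actin-binding gene Lsp1 (-1.40 ± 0.26, 0.0160), which fell in every strain, fell further. Chst11 alone differed in C57BL/6J (4.73 ± 0.82, 0.00648) and Ear10 alone in CC059/TauUnc. In CC003/Unc and CC025/GeniUnc 0 genes did (1331 and 627 at an unadjusted p under 0.05, edgeR; no other tool was run for this test).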
